A study of Homo sapiens with 3 samples.

How the data were processed

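Polyadenylated RNA from NB4 cells, an acute promyelocytic leukaemia cell line, was sequenced after expression of short hairpin RNAs (shRNAs). Per the labels, 1 library came from cells with a control hairpin that targets no gene, and 2 libraries came from cells with hairpins against ARID1B, a different hairpin in each (hairpins 2 and 3). Cells grew in RPMI medium with fetal bovine serum, and libraries were made with an Illumina TruSeq kit after polyA selection, per the labels' protocols. The labels do not say whether the libraries came from separate infections or cultures.

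The authors deposited a table of whole-number read counts per gene, not normalized, for 57773 Ensembl gene IDs. STAR, featureCounts and Cufflinks and the human build hg19 are named, without versions or order, per the submitters' processing notes. Which tool made the counts, the annotation release and whether strand was used are not given in the sources used here. The counts are whole and 24848 IDs had 0 counts in all 3 libraries. Because strand use is not given, the split of reads between overlapping genes, antisense genes included, is uncertain.

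Names were taken from GENCODE release 29, which named 52338 of the IDs. The unnamed IDs held 1.56% of the counts in the control library, 1.55% under hairpin 2 and 1.47% under hairpin 3, and they stayed in the library sizes and tests. GENCODE 29 describes another build than the one the counts were made on, so it served only for names, gene types, transcript length and GC content and for which genes share exons, and no coordinates are given. Where several IDs carried a symbol, the ID with most counts kept it.

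Total counts were 61640692 in the control library, 59997475 under hairpin 2 and 62954803 under hairpin 3. A gene with 3 counts, the most that a count of 0 allows, would stand at 0.0487, 0.05 and 0.0477 CPM, counts scaled to library size. Reads carry no molecular identifiers, so floors and counting intervals (95%) cover counting error only.

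Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group at its minimum count of 10, which left 20382 genes, and libraries were scaled by TMM factors (1.0074 for the control, 1.0024 for hairpin 2 and 0.9903 for hairpin 3). After estimateDisp, ARID1B shRNA was compared with control shRNA by the quasi-likelihood test (glmQLFit with legacy = FALSE, which is not the default of this version, and glmQLFTest), two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. With 2 libraries against 1, the fit had 1 residual degree of freedom. The spread came from the difference between the hairpins alone, and the lone control library was assumed to vary like them. The p-values therefore measure only the spread between these samples, which may be technical. The common biological coefficient of variation was 0.11 and the prior carried 14.8 degrees of freedom. Standard errors are the log2 fold change divided by the square root of the quasi-likelihood F statistic.

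Each hairpin library was also set against the control library as log2 CPM with a prior count of 2, without a test, for genes with a mean CPM of at least 1. Because both comparisons share the control, 100 simulated sets of 3 libraries with no change gave the values that the shared control produces by itself. The simulations used the fitted dispersions and, since these rest on the hairpins alone, dispersions 4 times as large. In both, the control varied like the hairpin libraries, so a control that differs more than they do was not simulated. A lone control library cannot be split.

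A set of 32 gene lists, fixed before the data were examined, was tested with camera in limma 3.58.1 (inter-gene correlation of 0.01, and estimated) and with fry, with Benjamini-Hochberg adjustment over the lists. With an estimated correlation camera uses the 1 residual degree of freedom, so hardly any list could pass, whatever its correlation. With the preset correlation its p rests on differences between genes, which are not replicate libraries. The fry test also draws its spread from the 1 residual degree of freedom, so few lists could pass it. For each hairpin, the list median was placed among 10000 random lists of the same size matched on mean expression in 40 bins. Symbols of the lists without a matching row, among them BOP1, UHRF1, CCL3 and CCL4, were not used.

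Named genes followed a rule fixed before the data were examined. ARID1B comes first, then the 12 higher and 12 lower genes with the largest log2 fold change among genes past the threshold with a mean CPM of at least 1 and the same direction under both hairpins. Up to 4 members of each list were named, called members first, and then ARID1A, ARID2, SMARCA4 and SMARCA2. The last part took the 5 genes furthest apart between the hairpins in each direction at a mean CPM of at least 5. Sex-linked marker genes, clone names, small RNAs and pseudogenes were left out. Some genes that the rule names are not reported here. Genes named outside this rule were chosen after their values were seen. These are MPO and XBP1, the list members given with at most 6 counts in each library, and, from the eosinophil, basophil and mast cell list, PRG3, SIGLEC8, TPSB2, CPA3, TPSAB1, MS4A3, CCR3 and IL5RA. From the azurophil granule list they include RNASE2, RNASE3, CTSD and GUSB.

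The procedure was tested on simulated counts with the means, library sizes and fitted dispersions of these samples and 200 changed genes, in a step that ran on 19912 genes. It recovered 33.8% of 68 genes changed by 1.5-fold, 83.3% of 66 changed by 2-fold and 98.5% of 66 changed by 4-fold, with 7 false calls. With nothing changed it called 0 of 19924 genes. The simulated control varied only as the hairpin libraries do. These counts of false calls therefore do not cover a lone control culture that differs more.

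Alternatives fixed beforehand were RLE and upper quartile factors, library size alone, no filter on low counts, a mean CPM of at least 1, DESeq2 1.42.0, limma-voom, the edgeR likelihood ratio test, the legacy quasi-likelihood fit, robust empirical Bayes, removal of the 10 most counted genes and a test against a fold change of 1.5. For each hairpin, prior counts of 0.5 and 5 and a mean CPM of at least 5 were tried. Leaving out either hairpin library leaves 1 library against 1, so it gives a value without a test. Alternatives chosen after seeing the data left out genes with at least 25% of their exon length inside exons of a gene with more counts, and joined the legacy fit with no filter on low counts. Tables were joined in Python 3.11.15 with pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.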

Results

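The effect of silencing ARID1B, a DNA-binding subunit of the BAF chromatin remodelling complex, was measured by RNA sequencing of NB4 cells. NB4 is a human acute promyelocytic leukaemia line that carries the PML-RARA fusion and is blocked at the promyelocyte stage of granulocyte development. The data comprised 3 libraries, 1 with a control hairpin and 2 with ARID1B hairpins. They held between 59997475 and 62954803 counts, and 28171 to 29270 genes had at least 1 count. Mitochondrial genes took 5.98% of the counts in the control library (95% Wilson interval 5.97 to 5.99), 5.74% under hairpin 2 (5.73 to 5.75) and 5.9% under hairpin 3 (5.9 to 5.91).

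ARID1B (ENSG00000049618) had 5268 counts in the control library, 2209 under hairpin 2 and 2234 under hairpin 3. This was 84.9 CPM in the control and 36.3 ± 0.635 CPM (SD, n = 2) in the knockdown libraries. ARID1B mRNA stood at 43.3% of the control level under hairpin 2 (exact 95% counting interval 41.2 to 45.5) and at 42.2% under hairpin 3 (40.2 to 44.4). On the log2 scale it fell by 1.23 with a standard error of 0.125 (edgeR quasi-likelihood test, adjusted p = 1.4e-05). Both knockdown libraries thus carried less of the targeted transcript than the control, by a similar amount. Its paralogue in the complex, ARID1A, had a log2 fold change of -0.18 ± 0.132 (SE), ARID2 of the related PBAF complex -0.24 ± 0.127, and the ATPase subunits SMARCA4 and SMARCA2 -0.06 ± 0.134 and -0.001 ± 0.127, none past the threshold in edgeR. Of 29 BAF and PBAF subunits measured, 2 fell, ARID1B and BCL11A (-1.20 ± 0.146), a zinc finger protein also known as a repressor of fetal globin genes. The count was the same adjusted over the list alone.

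With ARID1B silenced, 9 of 13 eosinophil, basophil and mast cell genes, 15 of 20 genes of mature myeloid receptors and the NADPH oxidase and 7 of 15 azurophil granule genes rose, and their list tests passed only with the preset correlation (camera adjusted p = 0.672 with an estimated correlation for each). With an estimated correlation camera had 1 degree of freedom, so hardly any list could pass, whatever its correlation. Of 20382 genes tested, 1119 were higher and 655 lower (1774 in all, 8.7%; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05), and 518 of the higher and 234 of the lower genes changed at least 2-fold. The share called higher was 63.1%, 53.8% with upper quartile factors and 73.7% with DESeq2. All 1774 lay on the same side of the control under both hairpins. As the spread in the test is the difference between the hairpins, genes on opposite sides could hardly be called. The shared side is therefore no separate sign of agreement. The largest rise was in EPX, the eosinophil peroxidase, 37.0-fold (log2 5.21 ± 0.382, edgeR adjusted p = 8.1e-07), from 643 counts to 31820 and 14820. HDC, which makes histamine, rose 23.5-fold (4.55 ± 0.345) and PRG2, the eosinophil major basic protein, 14.8-fold (3.88 ± 0.292). IL1RL1, the IL-33 receptor of mast cells and basophils, rose by 4.84 ± 0.513 on the log2 scale, from 17 counts to 647 and 313. Other large rises were in the kinase CDK15 (4.75), COL26A1 (4.57), GCSAML (4.21), the chemokine CCL2 (3.96), the sialic acid binding lectin SIGLEC7 (3.85), the lipase family member PNPLA1 (3.81) and the platelet integrin ITGA2B (3.80). PRG2 has 43% of its exon length in common with an overlapping gene annotated with more counts, and SIGLEC7 has close paralogues, so the counts of both are uncertain. Without a filter on low counts no gene passed (0 in edgeR, 3218 at an unadjusted p under 0.05, against 4226 in the filtered fit; 327 genes passed there with the legacy fit, a setting chosen after seeing the data), and with robust empirical Bayes 5 of the 12 largest rises passed, EPX, HDC, PRG2, IL1RL1, GCSAML, CCL2 and ITGA2B being lost (edgeR adjusted p = 0.291, 0.285, 0.0698, 0.131, 0.0738, 0.139 and 0.436; over the alternatives the p of EPX ranged from 4.6e-52 to 0.465).

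The largest falls were in the lipocalins LCN10 (-5.05 ± 0.406) and LCN6 (-5.03 ± 0.312), which went from 239 to 5 and 9 counts and from 451 to 13 and 14. Both share over 40% of their exon length with the same overlapping gene (44.8% and 44.1%), so they are not independent. The long non-coding RNA LINC01833 (-4.21 ± 0.335), the Wnt ligand WNT7B (-3.56 ± 0.319), the homeobox gene HOXC4 (-3.21 ± 0.34) and the cell surface antigen GPA33 (-3.19 ± 0.36) also fell. CCR2, the monocyte receptor for CCL2, fell from 257 counts to 18 and 38 (-3.17 ± 0.336, edgeR adjusted p = 1.9e-05), while its ligand was among the largest rises. Further large falls were in PRR15 (-2.71), the R-spondin receptor LGR4 (-2.60), the transporter ABCA13 (-2.56) and the Rac activator TIAM1 (-2.50). In edgeR 10 of the 12 largest falls passed with robust empirical Bayes, LGR4 and TIAM1 being lost (adjusted p = 0.0759 and 0.0638; over the alternatives the p of LGR4 ranged from 4.5e-25 to 0.465).

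**Figure D1:**
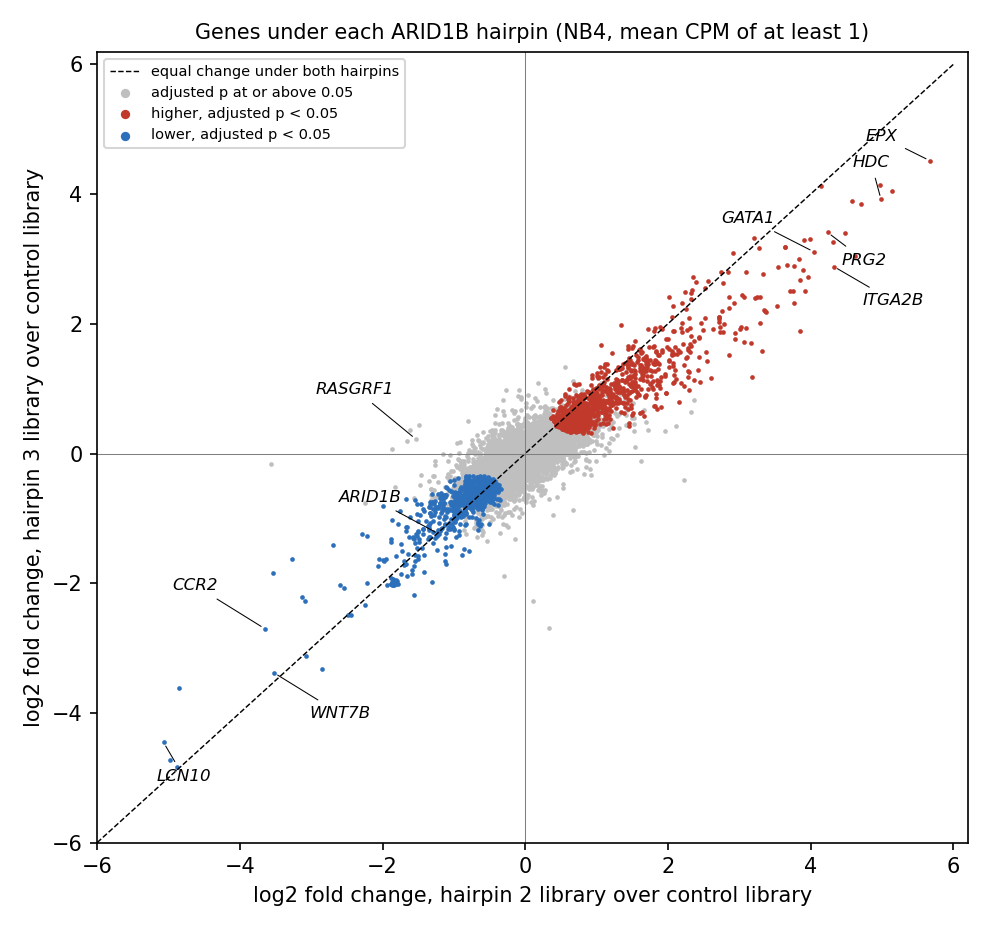
Log2 fold change of each gene with a mean CPM of at least 1, for the hairpin 2 library (horizontal axis) and the hairpin 3 library (vertical axis) over the same control library, with genes past the edgeR threshold in red (higher) or blue (lower) and others in grey. Genes called in either direction lie on the same side under both hairpins, since the test could hardly call others. Most called higher lie below the dashed line of equal change, as EPX does (5.67 under hairpin 2 and 4.52 under hairpin 3).

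Of 13 measured members of the eosinophil, basophil and mast cell list, 9 rose and 1 fell over all genes tested, and 10 rose and 1 fell adjusted over the list alone. Beside EPX, HDC and PRG2 these were the eosinophil protein PRG3 (3.11), the eosinophil lectin SIGLEC8 (2.72), the mast cell proteases TPSB2 (2.20), CPA3 (1.94) and TPSAB1 (1.71), and CLC, the Charcot-Leyden crystal protein. CLC had 3 counts in the control library and 127 and 26 in the knockdown libraries, a ratio of 43.7 under hairpin 2 (exact 95% counting interval 14.6 to 215) and of 8.63 under hairpin 3 (2.65 to 44.6). MS4A3, expressed in basophils and in granulocyte progenitors, fell (-0.54 ± 0.142), a call that was lost with DESeq2, with a mean CPM of at least 1 and against a fold change of 1.5. The receptors CCR3 and IL5RA had log2 fold changes of 0.93 ± 0.675 and 2.19 ± 0.709, from 9 and 5 control counts, and did not pass in edgeR. FCER1A had 0 counts in each library, which allows up to 0.0487 CPM in the control and 0.05 and 0.0477 CPM under hairpins 2 and 3. In camera the list passed upward (adjusted p = 1.8e-27), and the p ranged from 3.3e-29 to 0.672 over the alternatives (adjusted p = 0.672 with an estimated correlation). In fry, which also had only 1 residual degree of freedom, the adjusted p was 0.532. With robust empirical Bayes 5 of the 9 rises passed (PRG3, SIGLEC8, TPSB2, CPA3 and TPSAB1). TPSAB1 and TPSB2 are nearly identical, so the split of reads between them is uncertain.

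Neutrophil granule genes changed in both directions. Of 15 azurophil granule genes, which promyelocytes make, 7 rose and 1 fell, with the same counts adjusted over the list alone. The 7 were BPI, PRTN3, LYZ, RNASE2, RNASE3, CTSD and GUSB. RNASE2 and RNASE3 also encode eosinophil granule proteins, and CTSD and GUSB general lysosomal enzymes. The 7 rises are therefore not all particular to neutrophil granules or separate from the eosinophil genes above. BPI, the bactericidal permeability-increasing protein, rose from 115 counts to 812 and 813 (2.84 ± 0.215), proteinase 3 (PRTN3) by 2.11 ± 0.151 and lysozyme (LYZ) by 1.86 ± 0.279, while cathepsin G (CTSG) fell from 6837 counts to 1672 and 2183 (-1.81 ± 0.141). Myeloperoxidase (MPO), with 682719 control counts, had 0.23 ± 0.295 and did not pass. LYZ was lost with DESeq2 and with robust empirical Bayes in edgeR (adjusted p = 0.236 and 0.468; from 1.7e-11 to 0.47 over the alternatives). Among 11 measured genes of specific and gelatinase granules, which form later, 4 rose and 1 fell (7 and 1 adjusted over the list alone). MMP9 rose by 2.23 ± 0.21 and the defensin DEFA3, which has a near-identical copy in DEFA1, by 3.02 ± 0.559. The antimicrobial peptide gene CAMP went from 3 counts to 62 and 46, a ratio of 21.3 under hairpin 2 (exact 95% counting interval 6.97 to 106) and of 15.3 under hairpin 3 (4.91 to 76.8), and ABCA13 fell as given above. DEFA3 was lost with robust empirical Bayes (edgeR adjusted p = 0.124; from 2.5e-07 to 0.47 over the alternatives), where 3 of the 11 were higher. LTF, LCN2, CEACAM8 and CRISP3 of that list had at most 6 counts in any library. In camera the adjusted p was 4.6e-10 for the azurophil list, with a range of 4.0e-10 to 0.672 over the alternatives, and 3.2e-04 for the later granules, with a range of 2.9e-04 to 0.672, both upward (adjusted p = 0.672 with an estimated correlation for each).

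Of 20 measured receptors of mature neutrophils and monocytes and subunits of the NADPH oxidase, 15 rose and none fell (18 and 0 adjusted over the list alone; camera adjusted p = 7.2e-22, from 1.6e-22 to 0.672 over the alternatives, with adjusted p = 0.672 with an estimated correlation). The oxidase subunit NCF1 rose by 3.52 ± 0.444, the formyl peptide receptors FPR1 and FPR2 by 3.40 ± 0.771 and 2.72 ± 0.554, and the integrin ITGAX (CD11c) by 2.44 ± 0.237. NCF1 has near-identical pseudogenes, so its counts are uncertain, and its call was lost with robust empirical Bayes (edgeR adjusted p = 0.139; from 1.1e-14 to 0.47 over the alternatives). With that setting 7 of the 20 passed, and 8 with DESeq2. FCGR3B, CXCR1, CD177, S100A12 and TLR2, receptors and a calcium-binding protein of mature cells on the same list, had at most 6 counts in any library. Among 21 measured retinoic acid responsive genes, of interest because NB4 cells mature under retinoic acid, 7 rose and 0 fell (11 and 1 adjusted over the list alone), led by STRA6 (2.72 ± 0.524), CD52 (2.01 ± 0.33), PRAM1 (1.86 ± 0.201) and ICAM1 (1.76 ± 0.326). CYP26A1, a direct retinoic acid target, had 3, 4 and 3 counts. The camera adjusted p of this list was 9.7e-06, from 6.1e-06 to 0.672 over the alternatives (adjusted p = 0.672 with an estimated correlation), and 3 of the 21 passed with robust empirical Bayes and with DESeq2. STRA6 was lost with robust empirical Bayes (edgeR adjusted p = 0.124; from 1.5e-06 to 0.47 over the alternatives).

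**Figure D2:**
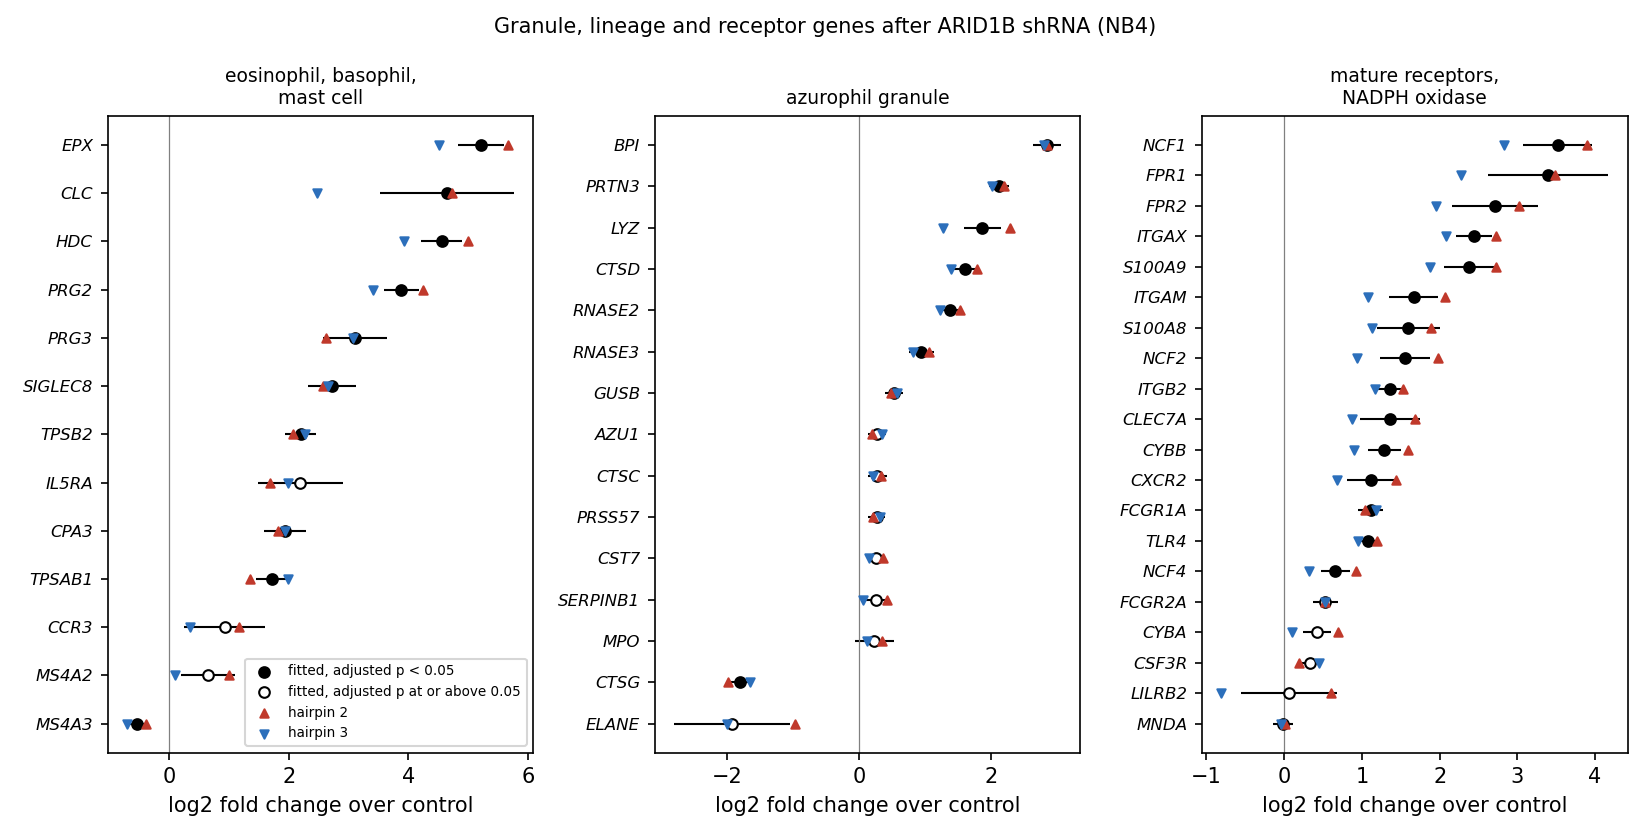
Log2 fold change over the control library (horizontal axis) of the measured members of the eosinophil, basophil and mast cell list, the azurophil granule list and the list of mature receptors and NADPH oxidase. Circles with standard error bars give the edgeR fit (filled where adjusted p was under 0.05), and triangles give hairpin 2 and hairpin 3 separately; EPX, BPI and NCF1 top the lists at 5.21, 2.84 and 3.52, and CTSG stands at -1.81.

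Regulators of myeloid identity moved in both directions. Of 22 myeloid transcription factors 4 rose and 3 fell (7 and 5 adjusted over the list alone). IRF8, which acts in monocyte and dendritic cell development, rose by 1.05 ± 0.216 and CEBPA, a driver of granulocyte fate, by 0.74 ± 0.141, while JUN fell (-0.91 ± 0.164). The median of that list was -0.03, its mean 0.14, and the list did not pass in camera (adjusted p = 0.749). Among 16 measured stem and progenitor genes GATA2 (1.38 ± 0.142) and LMO2 (0.62 ± 0.131) rose and the receptor FLT3 fell (-1.45 ± 0.185), 3 and 1 adjusted over the list alone (camera adjusted p = 0.256). CD34, a surface marker of stem cells, had 0 counts in each library. GATA1, the transcription factor of erythroid, megakaryocyte, eosinophil and mast cells, rose 12.9-fold, from 57 counts to 942 and 510 (log2 3.70 ± 0.374), and was the only riser among 4 measured erythroid markers. EPOR and ALAS2 had 0.22 ± 0.213 and 0.53 ± 0.647, and HBA1 and HBB had at most 1 count in any library. ITGA2B and GP1BB (0.60 ± 0.156) rose among 7 megakaryocyte and platelet markers, while PF4 and GP9 had 0 counts. With robust empirical Bayes GP1BB alone passed, and with DESeq2 ITGA2B alone (GP1BB adjusted p = 0.0592; from 0.013 to 1 over the alternatives). GP1BB shares 64.8% of its exon length with SEPT5, an overlapping gene with more counts. The erythroid and megakaryocyte lists had a camera adjusted p of 0.00536 and 0.0324, from 0.00446 and 0.0136 to 0.672 over the alternatives (adjusted p = 0.672 with an estimated correlation for both), and the megakaryocyte list also did not pass with library size alone (camera adjusted p = 0.0579). GATA1 did not pass with robust empirical Bayes (edgeR adjusted p = 0.0958; from 5.0e-22 to 0.47 over the alternatives). Of the marker lists of other blood and tissue cells, the monocyte and macrophage list had 3 of 9 higher, among them FCN1 (1.52 ± 0.26) and CD68 (0.88 ± 0.151), with 4 adjusted over the list alone. Its camera adjusted p was 6.9e-04, from 5.0e-04 to 0.675 over the alternatives (adjusted p = 0.675 with an estimated correlation). With robust empirical Bayes 1 of the 9, CD68, passed, and FCN1 was lost there and with DESeq2 (adjusted p = 0.367 and 0.31; from 1.0e-07 to 0.47 over the alternatives). CD68 shares 81.7% of its exon length with an overlapping gene. The T, NK and B cell list had 2 of 9 higher, CD3D (1.17 ± 0.197) and NKG7 (0.63 ± 0.185), and the epithelial, fibroblast and packaging cell list 1 of 6 lower, COL6A1 (-1.70 ± 0.35). NKG7 was lost with robust empirical Bayes, DESeq2, upper quartile factors and a mean CPM of at least 1 (edgeR adjusted p = 0.215 with the first, from 0.0159 to 1 over the alternatives) and COL6A1 with DESeq2 (adjusted p = 0.098; from 1.9e-04 to 0.47). Neither list passed in camera (adjusted p = 0.478 and 0.576). With a mean CPM of at least 1 the T, NK and B cell list passed (adjusted p = 0.0137 in camera; from 0.0137 to 0.749 over the alternatives). It had a median of 0.02, a mean of -0.004 and an upward test.

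Cytokine, chemokine and adhesion genes rose in part. Of 19 NF-kB targets and inflammatory cytokines 5 rose and 0 fell (the same adjusted over the list alone), with CCL2, IL1B (2.20 ± 0.47), ICAM1 and CXCL8 (0.98 ± 0.173) in the lead. IL1B was lost with a mean CPM of at least 1, and 3 of the 19 passed with robust empirical Bayes. Of 18 chemokine receptors and adhesion molecules 7 rose and 1, CCR2, fell (9 and 1 adjusted over the list alone), among them the integrin ITGB7 (2.10 ± 0.338) and the tetraspanin CD82 (1.71 ± 0.152). ITGB7 shares 42.1% of its exon length with ZNF740 on the other strand, and it and ICAM1 were lost with DESeq2 (adjusted p = 0.211 and 0.428) and with robust empirical Bayes in edgeR (0.43 and 0.538; over the alternatives from 3.4e-09 to 0.47 and from 2.1e-07 to 0.538). Both lists passed in camera, with an adjusted p of 9.0e-04 for the cytokine list and 1.9e-06 for the adhesion list, from 6.8e-04 and 1.6e-06 to 0.672 over the alternatives (adjusted p = 0.672 with an estimated correlation for both). CD74, the invariant chain of MHC class II, rose by 2.96 ± 0.477 from 32 counts to 335 and 157, the only riser of 5 measured class II genes. It was lost with robust empirical Bayes (edgeR adjusted p = 0.157; from 3.9e-09 to 0.47 over the alternatives), where 0 of the 5 passed (1 with DESeq2). Its transactivator CIITA had -0.05 ± 0.17, and HLA-DRA had 2, 5 and 3 counts. Among interferon response genes, OAS3 (-2.38 ± 0.456) and DDX58 (-0.62 ± 0.176) fell and IFI6 (1.83 ± 0.278) and CMPK2 (0.78 ± 0.215) rose, of 24 measured (3 higher and 5 lower adjusted over the list alone). With DESeq2 and with a mean CPM of at least 1 only IFI6 of these passed, OAS3, DDX58 and CMPK2 being lost in DESeq2 (adjusted p = 0.118, 0.18 and 0.153; over the alternatives from 8.8e-06 to 0.47, 0.0167 to 1 and 0.0225 to 0.881). The median of the interferon list was -0.34 under hairpin 2, at percentile 0.2 of matched random lists, and 0.15 under hairpin 3, at percentile 98.5. Among 21 immediate early genes 3 rose and 2 fell (4 and 5 adjusted over the list alone), with KLF2 at 1.62 ± 0.377, DUSP6 at 0.65 ± 0.162 and NR4A1 at -1.02 ± 0.196. KLF2 was lost with DESeq2 (adjusted p = 0.109; from 0.00172 to 0.465 over the alternatives) and DUSP6 with robust empirical Bayes (edgeR adjusted p = 0.0599; from 0.00207 to 1). Of 14 coagulation and fibrinolysis genes the urokinase gene PLAU rose (0.89 ± 0.155) and thrombomodulin (THBD) fell (-1.09 ± 0.194), 1 and 4 adjusted over the list alone. The class II, interferon, immediate early and coagulation lists did not pass in camera (adjusted p = 0.123, 0.576, 0.837 and 0.711). The immediate early and coagulation lists had medians above 0 (0.13 and 0.06) and a downward test, and the coagulation mean was -0.31.

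Of 16 unfolded protein response genes 7 rose and 0 fell (9 and 0 adjusted over the list alone). The calcium-binding chaperone CALR rose by 0.80 ± 0.197, from 88841 counts to 151451 and 153482, PDIA6 by 0.80 ± 0.144, HSPA5 (BiP) by 0.79 ± 0.157 and HERPUD1 by 0.73 ± 0.143. XBP1, a transcription factor of this response, had -0.04 ± 0.131. This list passed in camera (adjusted p = 6.1e-06), with p from 5.4e-06 to 0.672 over the alternatives (adjusted p = 0.672 with an estimated correlation), and 5 of the 16 passed with DESeq2 and 3 with a mean CPM of at least 1, where CALR was lost. Against a fold change of 1.5, which was tested in edgeR, 0 of the 16 passed. Of 19 integrated stress response and serine synthesis genes DDIT4 (1.08 ± 0.134) and WARS (0.75 ± 0.146) rose and 0 fell (3 and 0 adjusted over the list alone), and of 23 cholesterol synthesis genes 4 rose and 0 fell (5 and 0 adjusted over the list alone), INSIG1 (0.57 ± 0.13), MSMO1 (0.63 ± 0.158), EBP (0.53 ± 0.137) and DHCR7 (0.52 ± 0.147). Both passed in camera, at an adjusted p of 4.4e-04 and 0.00352, from 3.8e-04 and 0.00187 to 0.672 over the alternatives (adjusted p = 0.672 with an estimated correlation for both). With DESeq2 only EBP and INSIG1 of the cholesterol genes passed, with a mean CPM of at least 1 only INSIG1, and against a fold change of 1.5 in edgeR 0 of the 23 (DHCR7 was lost with upper quartile factors and robust empirical Bayes too, and MSMO1 and DHCR7 had a DESeq2 adjusted p of 0.0545 and 0.062, from 0.0113 to 1 and 0.0149 to 1 over the alternatives). Of 20 glycolysis and hypoxia genes the glucose transporter SLC2A3 (0.96 ± 0.158) and PFKFB3 (0.91 ± 0.168) rose and 0 fell (3 and 1 adjusted over the list alone). BCL2A1 (1.59 ± 0.248), BIK (0.95 ± 0.263) and BCL2L1 (0.55 ± 0.144) rose among 16 BCL2 family genes, the first and last of which restrain cell death and the other of which promotes it (4 and 1 adjusted over the list alone). With DESeq2 and with a mean CPM of at least 1 only BCL2A1 of these passed (DESeq2 adjusted p = 0.134 for BIK and 0.0591 for BCL2L1; from 0.0167 to 0.52 and 0.0146 to 1 over the alternatives). The death receptor TNFRSF10B (0.65 ± 0.139) rose among 16 p53 targets, the same count adjusted over the list alone, and the cell cycle inhibitor CDKN1A had 1.05 ± 0.347 from 50 control counts and did not pass. The glycolysis, BCL2 and p53 lists did not pass in camera (adjusted p = 0.256, 0.131 and 0.14), though the BCL2 list did with a mean CPM of at least 1 (adjusted p = 0.0363; from 0.0363 to 0.672 over the alternatives). Against a fold change of 1.5 in edgeR, further genes given above with a rise or fall did not pass, namely CLC, IRF8, CEBPA, JUN, LMO2, GP1BB, CD68, NKG7, CXCL8, DDX58, CMPK2, KLF2, DUSP6, NR4A1, PLAU, THBD, WARS, SLC2A3, PFKFB3, BIK, BCL2L1 and TNFRSF10B.

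Cell cycle, growth and respiration genes did not pass singly. In edgeR 0 of 21 G1/S and replication genes, 0 of 22 G2/M genes, 0 of 23 MYC targets and ribosome biogenesis genes, 0 of 28 nuclear encoded oxidative phosphorylation genes, 0 of 16 heat shock and chaperonin genes and 0 of 12 replication-dependent histones passed, over all genes or adjusted over the list alone. DESeq2 called 0 of each as well, and 1, 4, 1, 2, 1 and 0 of them had an unadjusted p under 0.05 in edgeR. In these polyA-selected libraries only 4 of the histones reached a mean CPM of at least 1, so their result says little about histone expression. The list medians were 0.10, 0.14, -0.04, 0.14, 0.06 and 0.37, and the heat shock list had a mean of -0.015 and a downward test. The G1/S median was -0.09 under hairpin 2 (percentile 8.6 of matched random lists) and 0.17 under hairpin 3 (99.1). The MYC median was -0.13 (1.1) and 0.03 (46.5), and the heat shock median -0.04 (42.2) and 0.06 (78.7). The G2/M, oxidative phosphorylation and histone medians were above 0 under both hairpins. The camera adjusted p values were 0.645, 0.0822, 0.576, 0.0594, 0.8 and 0.372, and that of the BAF and PBAF subunits was 0.0602. The oxidative phosphorylation list passed in camera with library size alone (adjusted p = 0.0451; from 0.0451 to 0.672 over the alternatives) and the BAF and PBAF list with a mean CPM of at least 1 (adjusted p = 0.034; from 0.034 to 0.672). Examples are CCNE2 (0.40 ± 0.174), NUSAP1 (0.38 ± 0.13), CAD (-0.26 ± 0.134), NDUFS3 (0.38 ± 0.13) and HSPB1 (-0.53 ± 0.178). HSPB1 passed in edgeR with upper quartile factors (adjusted p = 0.0456; from 0.0456 to 1 over the alternatives) and also with library size alone. Ribosomal protein genes also had 0 of 30 called (0 with DESeq2, 1 at an unadjusted p under 0.05), yet each of the 30 named in the list lay below the control, with a median of -0.21, and RPS6 at -0.44 ± 0.232 and RPL22 at -0.38 ± 0.158. As a list they passed in camera (adjusted p = 3.2e-04, downward), with p from 5.1e-05 to 0.752 over the alternatives (adjusted p = 0.752 with an estimated correlation). All ribosomal protein genes together took 9.58% of the counts in the control library (95% Wilson interval 9.57 to 9.59), 7.49% under hairpin 2 (7.49 to 7.5) and 8.53% under hairpin 3 (8.52 to 8.53). In all, 14 of the 32 lists passed in camera, 13 upward and 1 downward. None (0) passed with an estimated correlation (0 at an unadjusted p under 0.05) or in fry (3 at an unadjusted p under 0.05), which asks whether a list moves without comparing it with other genes. The fry test, too, had 1 residual degree of freedom (smallest adjusted p = 0.0952 in fry), so the lack of passing lists there says little. The result with an estimated correlation does not weigh gene correlation, as camera then had 1 degree of freedom. The estimate for the eosinophil, basophil and mast cell list was -0.077, below the preset 0.01. Its unadjusted camera p still went from 5.5e-29 to 0.0536. Of the other lists that passed, the integrated stress response (-0.053), adhesion (-0.007) and erythroid (-0.333) lists also had estimates below the preset. The rest had estimates above it, such as 0.867 for ribosomal proteins, 0.621 for mature receptors and 0.533 for the unfolded protein response. For those lists the preset may be too low and the camera p too small.

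**Figure D3:**
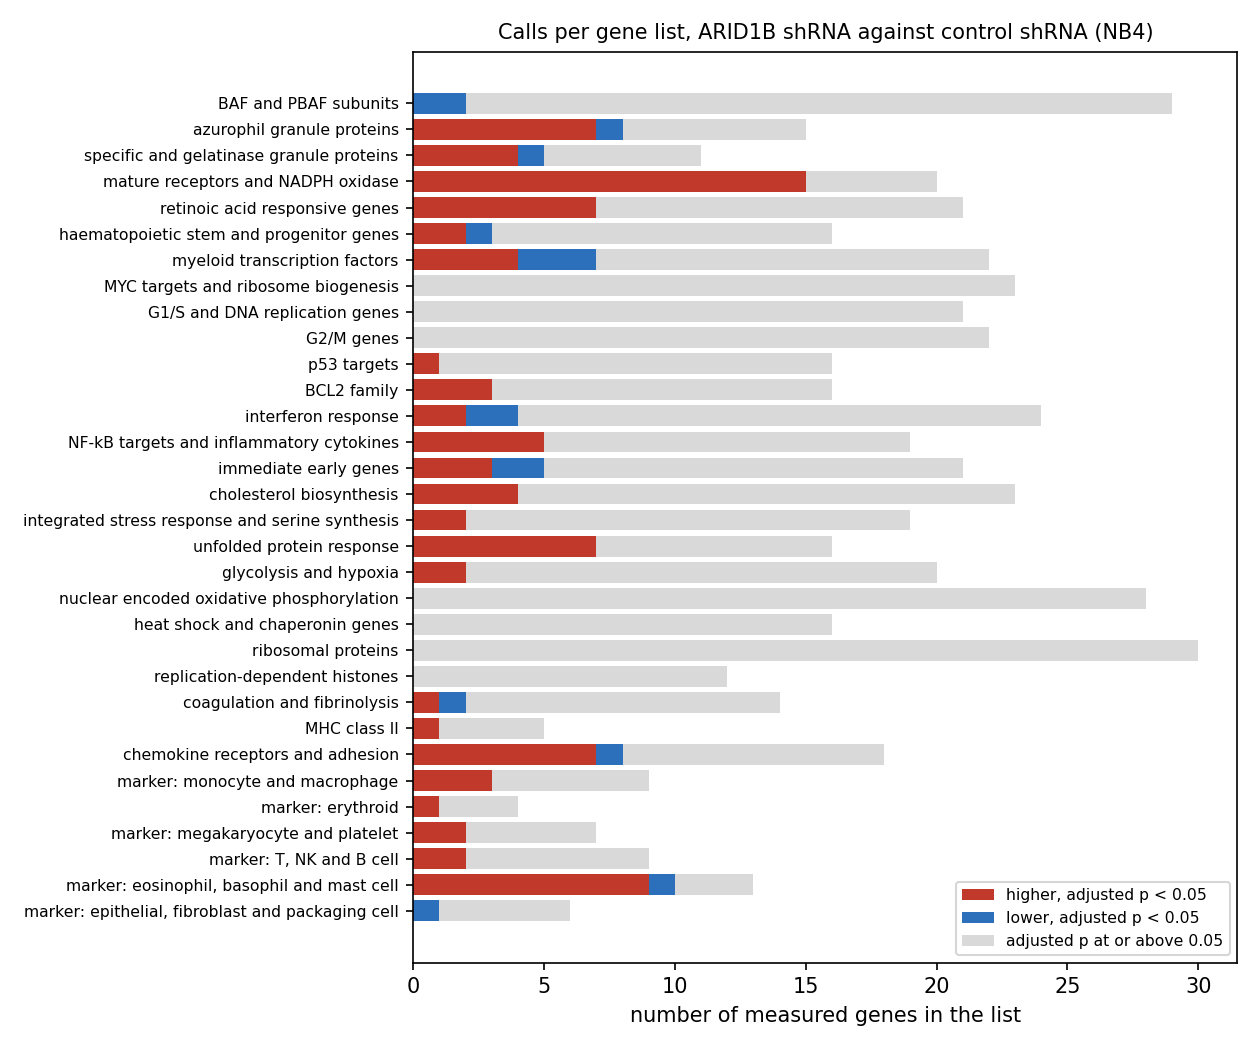
Number of measured genes in each of the 32 lists (horizontal axis) that were higher (red), lower (blue) or not past the edgeR threshold (grey) with ARID1B shRNA against control shRNA. The list of mature receptors and NADPH oxidase has most calls, 15 of 20 higher, and 7 lists have none.

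Set against the control library separately, the hairpins gave similar profiles that differed in size. Among 14980 genes with a mean CPM of at least 1, 328 were at least 2-fold higher and 128 at least 2-fold lower under both hairpins, and 0 were 2-fold in opposite directions. A further 348 genes were 2-fold away under hairpin 2 only and 57 under hairpin 3 only, differences that were not tested. With 1 library on each side these values have no replicate check. Unchanged libraries that shared a control gave on average 4.39 and 0.99 genes 2-fold higher or lower under both at the fitted dispersions, and 125 and 65.4 at dispersions 4 times as large. Independent lists of these sizes would share 12.5 and 2.92. Across genes, which are not independent replicates, the fold changes had a Pearson r of 0.877 (simulated 0.5) and a Spearman rho of 0.786 (simulated 0.473). Their covariance was 0.208 against 0.0331 simulated, or 0.12 at the larger dispersions. Both settings let the control vary only as the hairpin libraries do. How much of the excess comes from the lone control library, up to all of it, therefore cannot be told. The sign was the same in 79.5% of genes (simulated 66.6%).

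The fold changes under the hairpins were at least 2-fold apart for 108 genes, of which 56 were past the threshold. Clusterin (CLU) had 52 control counts, 711 under hairpin 2 and 269 under hairpin 3, with log2 fold changes of 3.77 and 2.32, and ITGA2B (4.33 and 2.88), MCTP2 (2.86 and 1.52) and the citrullinating enzyme PADI4 (3.53 and 2.28) were likewise higher under hairpin 2. CLEC5A, a myeloid lectin, was at 0.39 under hairpin 2 and -0.95 under hairpin 3. In the other direction RASGRF1 had 653 control counts, 217 under hairpin 2 and 766 under hairpin 3 (-1.54 and 0.22), HUNK -2.70 and -1.41, DNAJB5 -0.27 and 0.97, PTK7 -1.46 and -0.33, and RIMKLB -2.29 and -1.24. With 1 library of each hairpin these gaps were not tested.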

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

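Removal of genes sharing exons and the legacy fit without a filter were chosen after seeing the data, and the other alternatives before. The number of calls differed between settings, in a design with 1 residual degree of freedom. Against 1774 genes (1119 higher, 655 lower), a mean CPM of at least 1 gave 960 (622, 338), DESeq2 1052 (775, 277) with 3557 adjusted p-values not given, and a test against a fold change of 1.5 gave 457 (325, 132). Without a filter on low counts the count was 0 in each direction, with 3218 genes at an unadjusted p under 0.05, but 327 (218, 109) with the legacy fit, the default of this edgeR version. The prior degrees of freedom were 2.13 (5.45 with the legacy fit) without a filter and 6.84 at a mean CPM of at least 1 against 14.8. Without the filter ARID1B kept its log2 fold change of -1.23 and lost its call (edgeR adjusted p = 0.465; from 6.4e-15 to 0.465 over the alternatives). RLE, upper quartile factors, library size alone, limma-voom, the likelihood ratio test, the legacy fit, robust empirical Bayes, removal of the 10 most counted genes and removal of genes sharing exons gave between 1474 and 2066. The share called higher was 63.1%, 53.8% with upper quartile factors and 73.7% with DESeq2. No call changed sign in any of these 14 alternatives. Robust empirical Bayes kept 1467 of the 1774 calls. The 307 lost had a median gap of 0.49 between the hairpins against 0.19 for those kept, and DESeq2 kept 1048. At a mean CPM of at least 5, 180 genes were 2-fold higher and 44 lower under both hairpins, against 328 and 128, as fewer genes were tested. Prior counts of 0.5 and 5, RLE and library size alone stayed within 1.5 times. With an estimated correlation, where camera had 1 degree of freedom and hardly any list could pass, 0 of the 14 list calls remained. Under another setting 4 lists newly passed. The interferon and coagulation lists changed direction at a mean CPM of at least 1 (camera adjusted p = 0.757 for both; from 0.55 to 0.76 and 0.693 to 0.913 over the alternatives), and SMARCA2 changed sign with RLE and DESeq2 (0.014 in both), none of them past the threshold; the cause was not tested. Of 2444 values of 155 named genes under the alternatives, these 2 reversed, 242 fell short of the threshold, 92 of them without a filter in the planned fit, 24 newly passed it and 44 moved by at least the SD between the hairpins when 1 hairpin was left out. Such a move can arise where the hairpins nearly agree and the prior count shrinks the single-library value. COL26A1 had 4.57 in the fit and 4.14 and 4.13 under hairpins 2 and 3. The 44 are therefore no measure of dependence on 1 hairpin. Leaving out hairpin 2 gave an ARID1B log2 fold change of -1.24 and leaving out hairpin 3 gave -1.21, values without a test. No paired analysis was possible because the groups share no replicate number. Splits of the samples were not counted, as the control group has 1 library. At this depth, genes with few control counts, such as CLC and CAMP with 3, have folds known only within wide counting intervals, and only 33.8% of simulated 1.5-fold changes were recovered.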

Other observations

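All genes and tests here were chosen only after the results were seen, except the effect of scaling on the eosinophil genes and of GC content and length on the difference between the hairpins. Among gene families sharing a symbol stem, 4 passed an enrichment test, PCDHGA and PCDHGB downward (adjusted p = 1.2e-14 and 1.6e-06 in Fisher's exact test) and the sialic acid binding lectins and TNF ligands upward. Of 8 tested SIGLEC genes 7 rose (Fisher's exact test against 7.16% of all protein-coding genes, adjusted p = 1.9e-05 over 818 family tests), with SIGLEC10 at 2.66 ± 0.222 and SIGLEC6 at 2.44 ± 0.188, and 7 of 8 were also called with RLE, upper quartile factors, library size alone and robust empirical Bayes. Of 9 TNFSF genes 5 rose (adjusted p = 0.0377 in the same exact test), TNFSF14 by 1.72 ± 0.241 and TNFSF10 by 1.44 ± 0.163 among them, and 4 were called with upper quartile factors and with robust empirical Bayes. The 5 include a readthrough of TNFSF12 and TNFSF13, which shares their reads. TNFSF13, TNFSF12 and the readthrough were not called under every alternative. Over DESeq2, limma-voom, the scalings and the mean CPM filter, their highest adjusted p was 0.153, 0.169 and 0.213. Genes of 1 family are not independent, and close paralogues such as SIGLEC5 and SIGLEC14 share reads. The groups named next were picked by their values and have no enrichment test. HLA-B, HLA-C, HLA-G and B2M rose, HLA-B by 1.28 ± 0.155 (7035 counts to 18189 and 15456) and HLA-C by 1.39 ± 0.162, with B2M at 0.72 ± 0.174, while HLA-E (0.14 ± 0.136), TAP1 (-0.17 ± 0.14) and TAP2 (0.14 ± 0.13) did not pass and the peptide loading gene TAPBP fell (-0.49 ± 0.127). Reads of HLA genes depend on how close the alleles of the line are to the reference. B2M and TAPBP were not called under every alternative (highest adjusted p 0.0568 and 0.0649 over DESeq2, limma-voom, the scalings and the mean CPM filter).

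Single genes of cytokine receptors, transcription factors and eicosanoid enzymes were also picked by their values, without an enrichment test. CSF2RB, the chain shared by the receptors for IL-3, IL-5 and GM-CSF, rose 7.6-fold, from 497 counts to 4747 and 2667, IL9R by 3.20 ± 0.44 and CSF2RA by 0.85 ± 0.151, while IL5RA (2.19 ± 0.709) did not pass. The transcription factors GFI1B (1.63 ± 0.276), NFE2 (1.45 ± 0.139), ZBTB16 (1.22 ± 0.164), ID2 (1.83 ± 0.267) and IKZF2 (1.61 ± 0.164) rose beside GATA1 and GATA2. Of the enzymes of leukotriene and prostaglandin synthesis, ALOX5AP (5.65-fold), LTC4S (1.02 ± 0.211) and PTGS1 (1.01 ± 0.201) rose, and ALOX5 (1.49 ± 0.595) and HPGDS, with 2 control counts and 25 and 4 in the knockdown libraries, did not pass. With robust empirical Bayes CSF2RB, ALOX5AP and PTGS1 lost their calls (edgeR adjusted p = 0.273, 0.263 and 0.0682), as GATA1 did, while the other 6 transcription factors passed.

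The rise of 9 genes of the eosinophil, basophil and mast cell list is the pattern most worth following. Mature eosinophils or basophils mixed into the knockdown cultures would bring abundant transcripts such as CLC and their receptors, but the median CPM of CLC, CCR3, IL5RA and SIGLEC8 was at most 0.234% of that of EPX, PRG2 and HDC. Scaling moves all genes alike, and with other factors the median log2 fold change over genes with a mean CPM of at least 1 lay between -0.054 and 0.009. That of the 9 genes was at least 3.06 there, which argues against scaling. Because the factors differed little, trying them could hardly have given another result. Misassigned reads of the paralogue MPO are argued against by an EPX fold 31.6 times that of MPO. Whether the control library is unlike other NB4 cultures cannot be told apart from an effect of the knockdown, because there is only 1 control library. A candidate explanation that stays open is a shift of the cells toward an eosinophil or mast cell programme after loss of ARID1B. The rise was not limited to that programme, as 15 of 20 mature receptor and NADPH oxidase genes rose too. EPX, HDC, PRG2 and CLC lost their calls with robust empirical Bayes (edgeR adjusted p = 0.291, 0.285, 0.0698 and 0.557). Further control cultures would test whether the control library is unusual, but not by themselves whether loss of ARID1B is the cause.

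In these libraries 86.1% of the higher and 61.1% of the lower calls of at least 2-fold lay further from the control under hairpin 2 than under hairpin 3; genes are not replicates, and whether further cultures would differ was not tested. Scaling moves all genes alike and is argued against as the whole cause by a criterion revised repeatedly after the result was seen, since the gap between the hairpins (log2, hairpin 2 minus hairpin 3) had a median of 0.43 for the higher and -0.14 for the lower calls, 0.565 apart (95% bootstrap interval over genes 0.445 to 0.675). The GC content and length trend is argued against as the whole cause, since after removal of a linear trend on GC content and length the share over both directions was 78.4%, against 78.2% with centring on the mean alone, while the trend moved 1207 of 19359 genes from lying further under one hairpin to the other. Among the 731 calls of at least 2-fold with these values only 19 moved. The fitted trend differed between the hairpins by at most 0.214 (log2). In these 2 libraries themselves ARID1B mRNA was not measurably lower under hairpin 2. The difference was 0.036 (log2, hairpin 2 minus hairpin 3), with a 95% interval of -0.049 to 0.121 from counting alone. Whether cultures with hairpin 2 lose more ARID1B mRNA cannot be told from single libraries. With the common dispersion, which was added to this criterion after the result was seen, the 95% interval was -0.41 to 0.48. The time since infection, ARID1B protein and off-target effects of either hairpin may contribute and were not tested.

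All 21 tested members of the gamma protocadherin cluster fell, by between -2.30 and -1.66 on the log2 scale. The members share 2181 exon bases, a median of 40.2% of their exon length, and the ratio of the highest to the lowest count among them in the control library was 1.955 (286 to 559). This is consistent with reads in the shared exons being counted for every member, so the 21 calls may reflect a change in the shared part of the cluster and not 21 separate changes. Whether the use of any promoter of the cluster changed was not tested.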
